A study of Mus musculus with 87 samples.

How the data were processed

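RNA was measured by sequencing in sorted mouse bone marrow cells. Per the labels' protocols, each library was made from 1000 sorted cells with a SMARTer ultra low input kit and sequenced as 50 bp reads on an Illumina HiSeq instrument. The 78 RNA libraries comprise 72 from leukaemic mice and 6 from wild-type mice. The genomic DNA samples and the ES-cell ChIP samples of the series were not analysed here. Each leukaemic group has 2 biological pools of mice, A and B, with 1 to 3 technical libraries per pool.

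The deposited table gives FPKM per gene and library, made by the authors. Per the submitters' processing notes, bases were called with bcl2fastq 2.18, reads were aligned to mm10 with TopHat2 2.0.13, and FPKM were computed with Cufflinks 2.2.1. The series text instead names TopHat 2.1.1, Ensembl 80 gene models, HTSeq-count 0.6.0 and edgeR with an adjusted p under 0.001 as the authors' route to differential expression. Because the table holds FPKM, the first route was taken as its source, which was not tested. The counts of the second were not among the deposited values. All columns of values were mapped to a library. The table has 45316 genes and 127 repeated symbols. Of the 38186 genes above 0, 99.98% have values that are whole multiples of 1 step per library and gene within a tolerance of 0.02, and the reads in genes per library were estimated from these steps. Their range is given with the results. No pair of libraries is identical (0 pairs). The difference between technical libraries of a pool has a chi-square per gene of 4 at the lowest and 26.4 at the median over 62 pairs, so they vary by more than counting alone.

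For each library log2(FPKM + 1) was taken, and technical libraries were averaged to pools. Genes with a pool mean of at least 1 FPKM in at least 2 pools were tested (17882). All 30 leukaemic pools entered 1 linear model per gene in limma 3.58.1 under R 4.3.3, with 15 residual degrees of freedom and moderated variances (trend and robust options). The median standard error of a fold change between 2 groups is 0.44. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 with a fold above 1.5. For the comparisons with wild-type cells each wild-type group was entered as 1 unit. Of the comparisons, 22 were planned and 3 (the combination against low DXR) were added.

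A set of 27 gene lists with 425 entries, of which 420 are in the table, was tested in each comparison with camera, once with the preset correlation of 0.01 and once with an estimated one, and with fry. The lists are erythroid, neutrophil, monocyte and macrophage, B-cell, T-cell, NK and cytotoxic, megakaryocyte and platelet, and stromal and endothelial markers; stem and progenitor identity; cell cycle; Wnt targets; Notch targets; p53 targets; FOXO targets; BCL2 family; immune checkpoint; MHC class I; MHC class II; interferon response; chemokine and adhesion; drug efflux and targets; glycolysis; oxidative phosphorylation; mitochondrially encoded transcripts; ribosome biogenesis; immediate early genes; and sex-linked genes. Counts adjusted over the list alone use the p of the list's tested members only.

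Named genes were chosen by a fixed rule among the genes that passed, whose pools do not overlap and whose higher group averages at least 5 FPKM. The 8 largest and 8 smallest fold changes were taken in each main LSC comparison and 4 each way in others, leaving out predicted genes, receptor segments, ribosomal proteins, histones and small RNAs. The rule adds up to 4 members of each list with at least 3 passing genes or a camera adjusted p under 0.05, and Ctnnb1, Pten, Myc, Axin2, Lef1, Cd274, Havcr2 and Cd24a in every comparison. Among these, the genes quoted were mostly those whose call held when each pool was left out, a choice made after their values were seen. Listed-at-0 genes, Ddx3y and Xist were quoted on the same terms.

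The scripts were tested on simulations with 200 changed genes among 17882. For LSC after chemotherapy 3% of genes changed 2-fold, 37.3% at 4-fold and 57.6% at 8-fold were recovered, with 4 false calls among 69. For LSC given low DXR the shares were 4.5%, 34.3% and 63.6% (6 false of 74), for HSPC after chemotherapy 0%, 43.3% and 65.2% (6 of 78), for blasts after chemotherapy 0%, 23.9% and 68.2% (9 of 70), and for the difference of the chemotherapy effect 0%, 16.4% and 43.9% (3 of 43). A raised list was called in each of the 5 simulations and 0 of the 26 others. Gene correlation was not varied and thus not tested.

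The alternatives tried were a pseudocount of 0.1 FPKM, no filter, quantile scaling, every library as a unit, an adjusted p under 0.001, the pool letter as a block, leaving out each pool, leaving out the 2 shallowest pools, and fits of the compared cell types alone. Gene positions are on mm10. Other software was data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.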

Results

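The series holds RNA sequencing of sorted bone marrow cells from mice with leukaemia driven by Pten loss and activated beta-catenin. The sorted cells are of 3 kinds: leukaemia stem cells (LSC), haematopoietic stem and progenitor cells (HSPC) and blasts. Mice received vehicle, chemotherapy, low-dose doxorubicin (low DXR), clinical-dose doxorubicin (clinical DXR), or low DXR plus chemotherapy (the combination), and cells were sorted 10 days after the start of treatment. The 15 leukaemic groups have 2 biological pools of mice each, A and B, and 72 libraries in all. Another 6 libraries come from wild-type mice, 3 of HSPC and 3 of the cells labelled Lym. Per the series text each pool mixes 4 to 5 male and 4 to 5 female mice, and each library starts from 1000 cells. Vehicle pool A was taken in week 7 and vehicle pool B in week 9. The authors' table lists FPKM for 45316 genes.

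Reads in genes per library, in units of 1e6 (M), ran from 0.705 M to 22.618 M, with a median of 12.05 M. The clinical DXR groups of LSC (0.705 M and 4.02 M) and HSPC (1.095 M and 5.081 M) are the shallowest, with 1 library per pool. Libraries of a pool correlate at a median r of 0.977, libraries of the other pool of the same group at 0.973, and libraries of another cell type at 0.857. All tests below use 17882 genes and n = 2 pools per leukaemic group. Fold changes are differences of log2(FPKM + 1) ± standard error, a scale that understates changes of weakly expressed genes. FPKM values are means ± SD over 2 pools. A gene passed at an adjusted p under 0.05 with a fold above 1.5. Treatment comparisons of a cell type share their vehicle pools and so are not independent. Levels of the Hba, Hbb, H2, Tpsab1, Mcpt and Gzm genes are uncertain because 50 bp reads can fit several near-identical copies.

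Sex-linked transcripts divide the pools by treatment. Ddx3y, on the Y chromosome, lies at 1220 to 2030 FPKM in the 12 vehicle and chemotherapy pools, with a median of 1360. In the 18 pools given DXR, alone or in the combination, it lies at 0 to 662 FPKM with a median of 0.945, and 16 of them stand under 100. Xist, transcribed from the inactive X chromosome, has a median of 5.24 FPKM in the former pools and 78.9 in the latter. Every comparison of a DXR or combination group with vehicle or chemotherapy therefore carries this split as well.

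**Figure D1:**
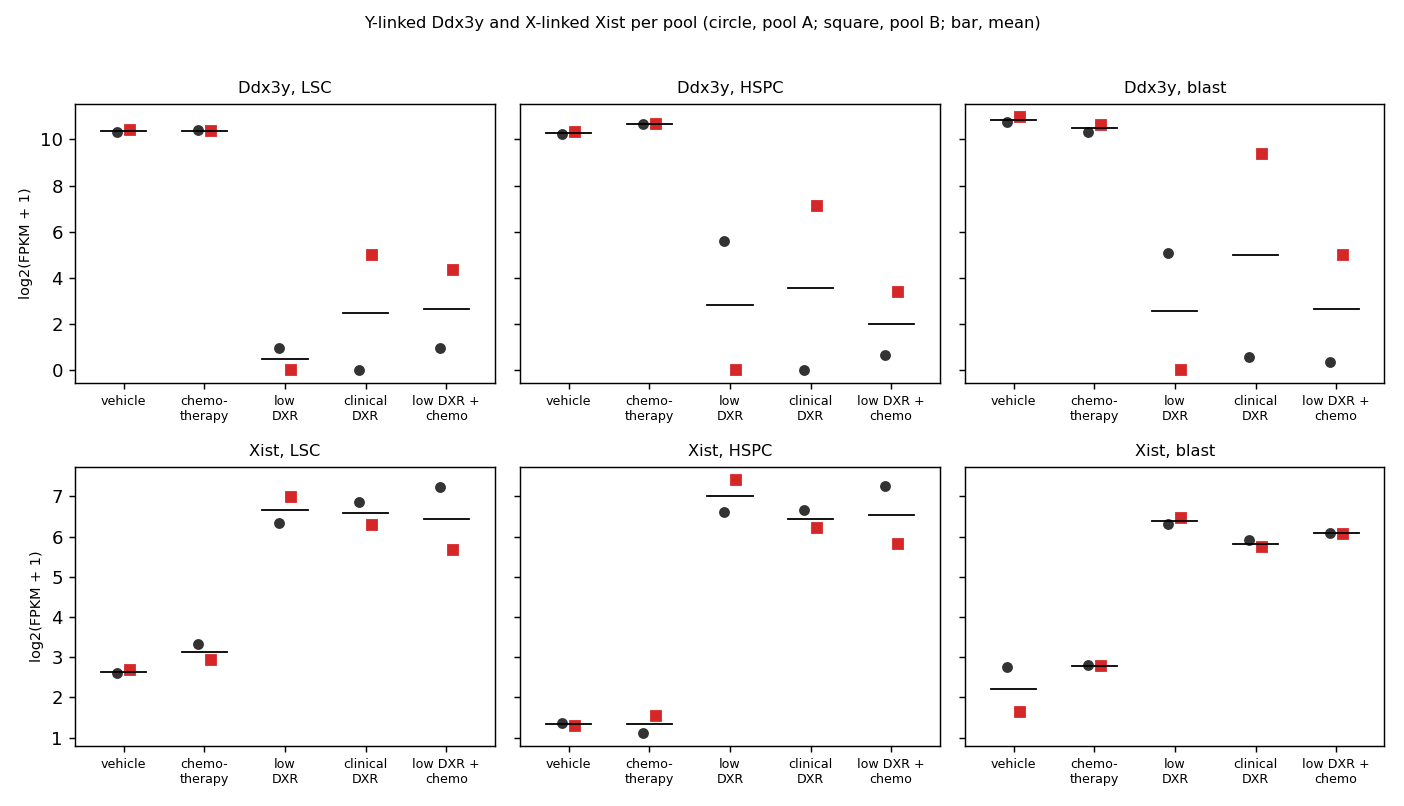
Ddx3y and Xist (FPKM, log scale) in each pool by cell type and treatment, circles pool A and squares pool B. Vehicle and chemotherapy pools lie at 1220 FPKM or above for Ddx3y, and 16 of the 18 DXR and combination pools lie under 100.

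What sets LSC apart from HSPC when no drug is given? Vehicle LSC carry an early erythroid programme and little of the stem cell, antigen presentation and platelet programmes of HSPC. They also hold less transcript for most glycolytic enzymes on the list. Of the erythroid markers, 8 of 15 were higher and 7 did not pass (8 passed adjusted over the list alone). They include Ermap (5.20 ± 0.91, adjusted p = 0.000401, 6940 ± 104 against 197 ± 70.9 FPKM), an erythroblast membrane protein, and Car1 (2.81 ± 0.56, adjusted p = 0.00123, 620 ± 254 against 84.2 ± 13.2 FPKM), a red cell carbonic anhydrase. Among stem and progenitor genes, 1 of 23 was higher, 17 were lower and 5 did not pass (19 passed adjusted over the list alone). Examples are Meis1 (-6.89 ± 0.71, adjusted p = 1.78e-06, 16.3 ± 4 against 1980 ± 15.9 FPKM), a transcription factor of stem cells, and Cd34 (-5.03 ± 0.43, adjusted p = 2.23e-07, 2.19 ± 0.0849 against 103 ± 2.12 FPKM), a progenitor surface sialomucin. In MHC class I presentation 8 of 13 were lower and 5 did not pass (11 passed adjusted over the list alone), including Psmb8 (-3.73 ± 0.24, adjusted p = 8.29e-09, 574 ± 6.21 against 7250 ± 796 FPKM), an immunoproteasome subunit. For MHC class II 9 of 9 were lower (9 passed adjusted over the list alone), for the megakaryocyte and platelet genes 8 of 9 were lower and 1 did not pass (8 passed adjusted over the list alone), and for glycolysis 1 of 14 was higher, 11 were lower and 2 did not pass (12 passed adjusted over the list alone). Pkm (-3.17 ± 0.48, adjusted p = 9.85e-05, 14.6 ± 5.34 against 136 ± 14.8 FPKM) is the pyruvate kinase that closes glycolysis. In ribosome biogenesis 5 of 15 were higher and 10 did not pass (6 passed adjusted over the list alone), led by Npm1 (1.91 ± 0.37, adjusted p = 0.00103, 2230 ± 211 against 590 ± 10.1 FPKM), a nucleolar chaperone. Fitting these cell types alone, 10 stem and progenitor genes were lower and 0 higher, and 1 ribosome biogenesis gene was higher.

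Smaller groups moved in the same comparison of vehicle LSC with HSPC. For the interferon response 10 of 20 were lower and 10 did not pass (10 passed adjusted over the list alone), for FOXO targets 7 of 16 were lower and 9 did not pass (9 passed adjusted over the list alone), and for immune checkpoints 5 of 19 were lower and 14 did not pass (6 passed adjusted over the list alone). Cd274, the gene of the checkpoint ligand PD-L1 on chromosome 19, is among the last (-2.55 ± 0.38, adjusted p = 8.19e-05). Immediate early genes (5 of 14 were lower and 9 did not pass, 6 passed adjusted over the list alone) and Notch targets (1 of 10 was higher, 3 were lower and 6 did not pass, 4 passed adjusted over the list alone) passed in part, and neither list passed camera (adjusted p = 0.0821 and adjusted p = 0.42). Of the mitochondrially encoded transcripts 3 of 10 were higher, 1 was lower and 6 did not pass (7 passed adjusted over the list alone). In the T-cell list 5 of 24 were higher, 2 were lower and 17 did not pass (7 passed adjusted over the list alone), and of the Wnt targets 2 of 17 were higher, 1 was lower and 14 did not pass (2 passed adjusted over the list alone), with Sp5 (3.78 ± 0.77, adjusted p = 0.00146), a transcription factor induced by beta-catenin, on the higher side. With quantile scaling 6 Wnt targets were higher and 0 lower, 10 T-cell genes were higher and 2 lower, and 3 FOXO targets were higher and 6 lower. Fitting these cell types alone, 1 T-cell gene was higher and 2 lower, and 3 checkpoint and 3 immediate early genes were lower. Ctnnb1, which encodes beta-catenin, stood at 758 ± 157 FPKM in LSC and 1280 ± 98.4 in HSPC and did not pass (-0.77 ± 0.34, adjusted p = 0.117). By camera with the preset correlation the ribosome biogenesis, erythroid, stem, MHC class I and glycolysis lists passed, and none did with an estimated correlation (adjusted p = 0.247, adjusted p = 0.211, adjusted p = 0.225, adjusted p = 0.139 and adjusted p = 0.29). In all, 4328 genes passed, 1093 higher and 3235 lower in LSC. The median of all genes lies at -0.25, and quantile scaling, which moves it by 0.34, gives 2444 higher and 2112 lower. Leaving out LSC pool B, HSPC pool A or HSPC pool B gives 2575, 2422 or 2463 genes.

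How do LSC differ from the blasts of vehicle mice? Blasts have a B-lymphoid and partly T-lymphoid profile with MHC class II, and LSC an erythroid and partly dividing one. Of the erythroid markers 14 of 15 were higher and 1 did not pass (14 passed adjusted over the list alone), among them Gata1 (7.72 ± 0.87, adjusted p = 2.78e-06, 366 ± 41.9 against 1.59 ± 1.7 FPKM), the master regulator of red cell genes. Of the B-cell markers 10 of 11 were lower and 1 did not pass (10 passed adjusted over the list alone), among them Cd79b (-9.37 ± 1.32, adjusted p = 3e-05, 26 ± 6.8 against 14700 ± 326 FPKM), a chain of the B-cell receptor. In the T-cell list 1 of 24 was higher, 20 were lower and 3 did not pass (23 passed adjusted over the list alone), and for MHC class II 9 of 9 were lower (9 passed adjusted over the list alone). Of the NK and cytotoxic genes 8 of 11 were lower and 3 did not pass (10 passed adjusted over the list alone). In the cell cycle list 10 of 25 were higher and 15 did not pass (11 passed adjusted over the list alone), and 18 were higher with quantile scaling, with Mki67 (2.61 ± 0.36, adjusted p = 2.48e-05, 273 ± 18.9 against 44 ± 4.59 FPKM), a mark of dividing cells. Among Wnt targets 2 of 17 were higher, 7 were lower and 8 did not pass (9 passed adjusted over the list alone), or 3 higher and 4 lower with quantile scaling. Both nuclear partners of beta-catenin were lower, Lef1 (-3.35 ± 0.55, adjusted p = 0.000134, 56.8 ± 41.5 against 519 ± 190 FPKM) and Tcf7 (-3.85 ± 0.67, adjusted p = 0.000229). The erythroid, B-cell and MHC class II lists passed camera with the preset correlation and each has adjusted p = 0.0775 with an estimated correlation. The T-cell list has adjusted p = 0.149 and the cell cycle list adjusted p = 0.255 with an estimated correlation. In all 5704 genes passed, 2039 higher and 3665 lower in LSC, and 3755 passed without blast pool B. The median of all genes lies at -0.20, and quantile scaling, a shift of 0.25, gives 3352 higher and 2820 lower.

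What do leukaemic cells show against wild-type cells? Each wild-type group was entered as a single unit, so its mean has no SD over pools. The spread in these tests comes wholly from leukaemic pools, and a wild-type unit is assumed to vary as they do. Against the lone wild-type HSPC unit, single platelet and B-lineage genes of vehicle HSPC passed: Gp1bb (3.45 ± 0.33, adjusted p = 5.61e-06, 16.2 ± 0.274 against 0.572 FPKM), a platelet receptor chain, was higher and Ebf1 (-3.65 ± 0.42, adjusted p = 4.94e-05, 0.226 ± 0.135 against 14.4 FPKM), a B-lineage transcription factor, was lower. Fcer1a, a chain of the mast cell IgE receptor, stood at 98.4 ± 23.4 FPKM in leukaemic HSPC and was listed at 0 in wild-type HSPC. By list, B-cell markers (2 of 11 were lower and 9 did not pass, 4 passed adjusted over the list alone), megakaryocyte genes (1 of 9 was higher and 8 did not pass, 5 passed adjusted over the list alone) and FOXO targets (0 of 16 passed, 1 passed adjusted over the list alone) passed camera, and did so with an estimated correlation as well (adjusted p = 0.0256, adjusted p = 0.00159 and adjusted p = 0.0217). In this comparison 217 genes passed, 115 higher and 102 lower in leukaemic HSPC. That balance turns with no filter (136 and 224), without the 2 shallow pools (225 and 262), with every library as a unit (883 and 1029), at an adjusted p under 0.001 (33 and 40) and without wild-type library 3 (115 and 117). Vehicle blasts exceeded wild-type Lym cells in part of the Wnt targets and part of the cell cycle genes: Sp5 (7.23 ± 0.94, adjusted p = 0.000194, 352 ± 196 against 2.96 FPKM) and Wif1 (6.89 ± 1.02, adjusted p = 0.00063, 166 ± 157 against 0.0518 FPKM), a secreted Wnt inhibitor. Of the Wnt targets 2 of 17 were higher and 15 did not pass (4 passed adjusted over the list alone), and of the cell cycle genes 3 of 25 were higher and 22 did not pass (11 passed adjusted over the list alone) (each list adjusted p = 0.412 with an estimated correlation). Here 536 genes passed, 411 higher and 125 lower in blasts, and 240 passed without blast pool B. The median of all genes lies at 0.15, and quantile scaling, a shift of -0.20, gives 300 higher and 188 lower.

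What does chemotherapy do to LSC? Part of the neutrophil, monocyte, MHC class I and glycolysis genes rose. Mean erythroid levels were lower, at 5.81 to 6.26 over libraries against 7.13 to 7.51 with vehicle. Of the neutrophil markers 9 of 16 rose and 7 did not pass (13 passed adjusted over the list alone), including Elane (5.29 ± 0.71, adjusted p = 8.41e-05, 567 ± 36 against 17.3 ± 14.4 FPKM), the elastase of promyelocyte granules, and Fcnb (3.84 ± 0.71, adjusted p = 0.00124, 29 ± 8.74 against 1.03 ± 0.277 FPKM), a secreted ficolin. Of the monocyte genes 6 of 16 rose and 10 did not pass (10 passed adjusted over the list alone), including Lyz2 (4.23 ± 0.70, adjusted p = 0.000573), the macrophage lysozyme. In MHC class I presentation 9 of 13 rose and 4 did not pass (10 passed adjusted over the list alone), with Psmb8 (2.84 ± 0.24, adjusted p = 8.47e-07, 3900 ± 170 against 574 ± 6.21 FPKM), and in glycolysis 9 of 14 rose and 5 did not pass (10 passed adjusted over the list alone), with Pkm (3.68 ± 0.48, adjusted p = 6.95e-05, 194 ± 14.6 against 14.6 ± 5.34 FPKM). Among chemokine and adhesion genes 7 of 15 rose and 8 did not pass (9 passed adjusted over the list alone). Of the T-cell genes 10 of 24 rose, 1 fell and 13 did not pass (19 passed adjusted over the list alone), but with quantile scaling 2 rose and 1 fell. The progenitor gene Cd34 (3.43 ± 0.43, adjusted p = 4.71e-05, 33.2 ± 3.43 against 2.19 ± 0.0849 FPKM) rose. Lef1 (1.47 ± 0.55, adjusted p = 0.0845), Myc (1.31 ± 0.44, adjusted p = 0.0553) and Ctnnb1 (0.46 ± 0.34, adjusted p = 0.436) did not pass.

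For LSC after chemotherapy the neutrophil, monocyte, MHC class I and glycolysis lists passed camera only with the preset correlation (adjusted p = 0.394, adjusted p = 0.438, adjusted p = 0.367 and adjusted p = 0.385 with an estimated correlation). In all 2460 genes passed, of which 2248 rose and 212 fell. The median of all genes lies at 0.39. Quantile scaling, a shift of -0.47, gives 1003 that rose and 1138 that fell. Without chemotherapy pool A or B, 986 or 1208 passed, and without vehicle pool A or B, 1178 or 1562. A fit of the LSC pools alone passed 619. There 6 neutrophil, 4 monocyte, 4 MHC class I, 3 glycolysis, 2 chemokine and adhesion and 0 T-cell genes rose, and 0 erythroid genes fell.

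What does low DXR do to LSC? Most T-cell genes and part of the Wnt, checkpoint, monocyte and MHC class II genes rose, and part of the erythroid and ribosome assembly genes fell. Of the T-cell list 17 of 24 rose, 1 fell and 6 did not pass (18 passed adjusted over the list alone), including Lck (5.00 ± 0.62, adjusted p = 1.43e-05, 565 ± 190 against 20.3 ± 17 FPKM), the kinase of T-cell receptor signalling. Of the Wnt targets 8 of 17 rose, 3 fell and 6 did not pass (11 passed adjusted over the list alone), including Lef1 (4.18 ± 0.55, adjusted p = 2.41e-05, 918 ± 314 against 56.8 ± 41.5 FPKM), on chromosome 3, and Tcf7 (5.34 ± 0.67, adjusted p = 1.55e-05, 1070 ± 264 against 39.9 ± 43.9 FPKM), on chromosome 11. Ctnnb1 did not pass (0.90 ± 0.34, adjusted p = 0.0541). Of the checkpoint genes 10 of 19 rose, 1 fell and 8 did not pass (11 passed adjusted over the list alone), including Cd274 (2.33 ± 0.38, adjusted p = 0.000158, 9.2 ± 1.11 against 1.09 ± 0.33 FPKM) and Pdcd1 (5.39 ± 0.74, adjusted p = 3.41e-05), which encodes the receptor PD-1. Of the p53 targets 10 of 24 rose, 1 fell and 13 did not pass (11 passed adjusted over the list alone), with Ddb2 (5.18 ± 0.79, adjusted p = 9.23e-05), a DNA damage sensor, and Mdm2 (1.97 ± 0.39, adjusted p = 0.00079). In glycolysis 10 of 14 rose, 1 fell and 3 did not pass (13 passed adjusted over the list alone), in MHC class I 8 of 13 rose and 5 did not pass (8 passed adjusted over the list alone), and in ribosome biogenesis 8 of 15 fell and 7 did not pass (9 passed adjusted over the list alone), with Npm1 (-2.79 ± 0.37, adjusted p = 2.86e-05, 327 ± 97.3 against 2230 ± 211 FPKM).

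Of the monocyte genes 8 of 16 rose and 8 did not pass (8 passed adjusted over the list alone) and of MHC class II 6 of 9 rose and 3 did not pass (7 passed adjusted over the list alone) in LSC given low DXR (adjusted p = 0.533 and adjusted p = 0.519 with an estimated correlation). Fitting LSC pools alone, 3 monocyte, 3 MHC class II and 5 MHC class I genes rose and 5 ribosome biogenesis genes fell, and of the Wnt targets 6 rose and 1 fell. The erythroid list split in LSC given low DXR: 5 of 15 rose, 6 fell and 4 did not pass (12 passed adjusted over the list alone). Alas2 (7.68 ± 0.82, adjusted p = 4.37e-06, 347 ± 230 against 0.529 ± 0.0637 FPKM), a haem enzyme of late erythroblasts, rose, while the earlier markers Ermap (396 ± 508 against 6940 ± 104 FPKM) and Car1 (-3.87 ± 0.56, adjusted p = 6e-05) fell. Xist (4.05 ± 0.48, adjusted p = 1.03e-05, 102 ± 32.3 against 5.24 ± 0.239 FPKM) rose and Ddx3y (-9.87 ± 2.64, adjusted p = 0.00814, 0.475 ± 0.671 against 1310 ± 58.2 FPKM) fell with the T-cell, Wnt and erythroid changes. The camera calls for T-cell, checkpoint, glycolysis, MHC class I and ribosome biogenesis genes were all lost, each at adjusted p = 0.452 with an estimated correlation. In all 5536 genes passed, 3654 that rose and 1882 that fell, and 3648 passed without low DXR pool A. The median of all genes lies at 0.15, and quantile scaling, a shift of -0.22, gives 2799 that rose and 3090 that fell.

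**Figure D2:**
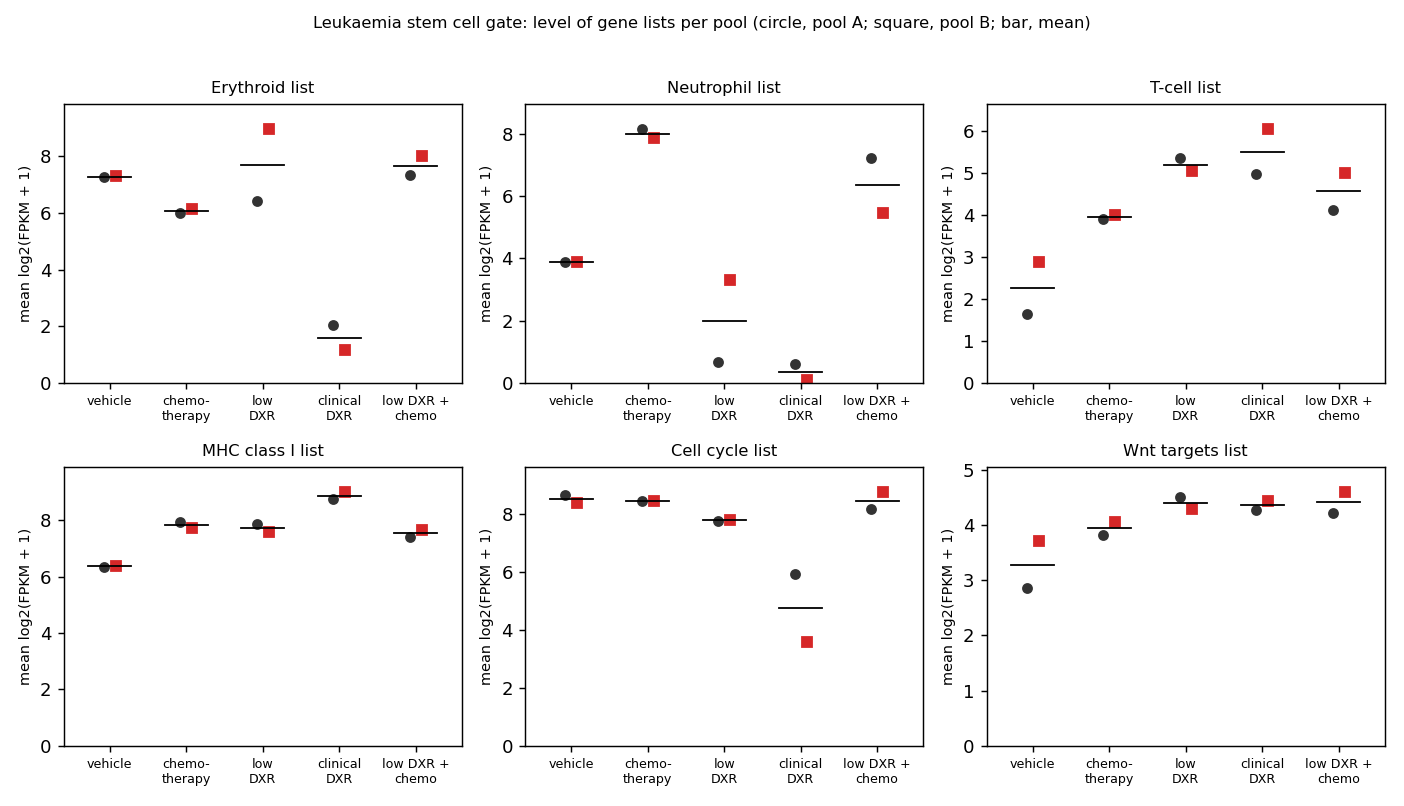
Mean log2(FPKM + 1) of gene lists in each LSC pool by treatment, circles pool A, squares pool B, bars the mean of 2 pools. The neutrophil list runs from 3.40 to 4.22 over vehicle libraries and from 7.49 to 8.76 after chemotherapy. After low DXR it runs from 0.66 to 3.29, after clinical DXR from 0.08 to 0.61 and after the combination from 4.65 to 7.89.

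What does the clinical dose do to LSC? Most of the cell cycle and erythroid markers fell, and most of the T-cell and NK markers rose. Of the cell cycle genes 18 of 25 fell and 7 did not pass (18 passed adjusted over the list alone), with Ube2c (-9.28 ± 0.45, adjusted p = 2.89e-10, 0.418 ± 0.591 against 882 ± 345 FPKM), a mitotic ubiquitin enzyme, and Mki67 (-5.44 ± 0.36, adjusted p = 6.21e-09, 5.56 ± 2.68 against 273 ± 18.9 FPKM). Without the 2 shallow pools 3 of these genes rose and 16 fell. Plk1, a mitotic kinase, was listed at 0 in both clinical DXR pools. Of the erythroid markers 13 of 15 fell and 2 did not pass (13 passed adjusted over the list alone), with Klf1 (-6.98 ± 0.63, adjusted p = 1.45e-07), and Ermap and Car1 were listed at 0 in both clinical DXR pools. Cma1 (13.23 ± 1.65, adjusted p = 4.55e-06, 15500 ± 2210 against 1.04 ± 1.48 FPKM) and Cpa3 (9.44 ± 0.65, adjusted p = 1.09e-08, 5260 ± 224 against 8.46 ± 1.8 FPKM), a pair of mast cell proteases, rose, but no list of mast cell genes was tested. In the T-cell list 18 of 24 rose, 1 fell and 5 did not pass (21 passed adjusted over the list alone), in the NK and cytotoxic list 8 of 11 rose and 3 did not pass (8 passed adjusted over the list alone), and in the stromal and endothelial list 4 of 8 rose and 4 did not pass (4 passed adjusted over the list alone). Of the drug efflux pumps and drug targets 6 of 13 rose, 2 fell and 5 did not pass (9 passed adjusted over the list alone): Abcb1b (4.68 ± 0.33, adjusted p = 1.43e-08, 350 ± 186 against 12.8 ± 6.43 FPKM), a pump that exports doxorubicin, rose, and Top2a (-6.00 ± 1.04, adjusted p = 0.000124), the enzyme doxorubicin poisons, fell. Of the BCL2 family 6 of 13 rose, 2 fell and 5 did not pass (8 passed adjusted over the list alone), with Bcl2 (4.00 ± 0.40, adjusted p = 4.2e-07) and Bax (2.30 ± 0.43, adjusted p = 0.000279). Fitting LSC pools alone, 3 drug efflux and target genes rose and 1 fell, and in the BCL2 family 4 rose and 1 fell.

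In LSC given the clinical dose Ctnnb1 (1.79 ± 0.34, adjusted p = 0.000317, 2650 ± 782 against 758 ± 157 FPKM), its nuclear partner Lef1 (3.93 ± 0.55, adjusted p = 1.41e-05, 796 ± 370 against 56.8 ± 41.5 FPKM) and its target Myc (1.98 ± 0.44, adjusted p = 0.00122) rose. The rise of Lef1 was not separated from the share of T-lineage cells. Cd274 (3.32 ± 0.38, adjusted p = 1.75e-06, 19.5 ± 5.41 against 1.09 ± 0.33 FPKM) rose too, and of the checkpoint list 11 of 19 rose, 1 fell and 7 did not pass (13 passed adjusted over the list alone). In oxidative phosphorylation 2 of 20 rose, 9 fell and 9 did not pass (12 passed adjusted over the list alone), and of the FOXO targets 10 of 16 rose, 1 fell and 5 did not pass (12 passed adjusted over the list alone). Xist (3.97 ± 0.48, adjusted p = 3.28e-06) rose and Uty (-3.59 ± 0.89, adjusted p = 0.00285) fell with the T-cell and cell cycle changes. The cell cycle, erythroid, T-cell and NK lists passed camera only with the preset correlation (adjusted p = 0.273, adjusted p = 0.25, adjusted p = 0.273 and adjusted p = 0.434 with an estimated correlation). In all 7808 genes passed, 4419 that rose and 3389 that fell. Quantile scaling gives 3894 that rose and 4153 that fell.

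Does the clinical dose differ from the low dose in LSC? It left less of most cell cycle and erythroid genes and more of the NK list and part of the stem cell list. In the cell cycle list 16 of 25 fell and 9 did not pass (17 passed adjusted over the list alone), with Ube2c (-8.44 ± 0.45, adjusted p = 1.18e-09) and Mki67 (-3.67 ± 0.36, adjusted p = 1.84e-06), and in the erythroid list 12 of 15 fell and 3 did not pass (12 passed adjusted over the list alone). Fitting LSC pools alone, 9 cell cycle genes fell, and without the 2 shallow pools 6 rose and 12 fell. In the NK list 8 of 11 rose and 3 did not pass (9 passed adjusted over the list alone), and in the stem list 9 of 23 rose and 14 did not pass (9 passed adjusted over the list alone), with Kit (3.92 ± 0.45, adjusted p = 9.41e-06), a receptor of stem and mast cells. Cma1 (8.03 ± 1.65, adjusted p = 0.00188, 15500 ± 2210 against 220 ± 301 FPKM), the mast cell protease, rose as well, by 5.15 without low DXR pool A. Abcb1b (2.22 ± 0.33, adjusted p = 0.000129, 350 ± 186 against 70.5 ± 21.1 FPKM) stood above its low-dose level, and of its drug efflux and target list 3 of 13 rose, 1 fell and 9 did not pass (4 passed adjusted over the list alone). Lef1 (-0.25 ± 0.55, adjusted p = 0.821), Cd274 (0.99 ± 0.38, adjusted p = 0.0689) and Ctnnb1 (0.89 ± 0.34, adjusted p = 0.0688) did not pass between doses. None of the 4 list calls held (adjusted p = 0.337, adjusted p = 0.19, adjusted p = 0.428 and adjusted p = 0.261 with an estimated correlation). In all 3943 genes passed, 1763 higher and 2180 lower at the clinical dose, and 2310 passed without low DXR pool B. The median of all genes lies at -0.08, and quantile scaling, a shift of 0.13, gives 2118 higher and 2041 lower.

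What does the combination do to LSC? Many T-cell, glycolysis and MHC class I genes and part of the Wnt and neutrophil genes passed in the fit of all cell types, and hardly any did in a fit of the LSC pools alone. In the T-cell list 16 of 24 rose, 1 fell and 7 did not pass (17 passed adjusted over the list alone), in glycolysis 10 of 14 rose and 4 did not pass (13 passed adjusted over the list alone), in MHC class I 8 of 13 rose and 5 did not pass (10 passed adjusted over the list alone) and in the checkpoint list 9 of 19 rose and 10 did not pass (10 passed adjusted over the list alone). Of the Wnt targets 8 of 17 rose and 9 did not pass (9 passed adjusted over the list alone), and of the neutrophil markers 5 of 16 rose and 11 did not pass (8 passed adjusted over the list alone). With quantile scaling 5 Wnt targets rose and 1 fell, and 1 neutrophil marker rose. The change of Psmb8 (3.06 ± 0.24, adjusted p = 6.95e-07, 4730 ± 985 against 574 ± 6.21 FPKM) passed, as did that of Ly6c2 (2.69 ± 0.45, adjusted p = 0.000686, 2120 ± 254 against 339 ± 15.5 FPKM). Lef1 (2.83 ± 0.55, adjusted p = 0.00211, 391 ± 238 against 56.8 ± 41.5 FPKM) also passed, but lost its call without combination pool B (2.16) or vehicle pool A (2.01), and Cd274 (1.89 ± 0.38, adjusted p = 0.0027) lost it without combination pool B (1.15). Uty (-3.62 ± 0.89, adjusted p = 0.0102) fell beside these changes, and lost its call without combination pool B (-3.20), vehicle pool A (-3.77) or vehicle pool B (-3.48). The T-cell list has adjusted p = 0.413, glycolysis adjusted p = 0.409 and the Wnt list adjusted p = 0.431 with an estimated correlation. In all 2618 genes passed, 2017 that rose and 601 that fell, with 4289 without combination pool A, 1048 without combination pool B, 1097 without vehicle pool A and 1553 without vehicle pool B. A fit of the LSC pools alone passed 48, with 0 T-cell, glycolysis, Wnt, checkpoint or neutrophil genes and 1 MHC class I gene among them. The median of all genes lies at 0.25, and quantile scaling, a shift of -0.29, gives 1245 that rose and 1582 that fell.

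Does adding low DXR to chemotherapy change LSC? Few genes passed: 28 higher and 193 lower in the combination, 221 in all. In the sex-linked list 1 of 5 was higher, 2 were lower and 2 did not pass (5 passed adjusted over the list alone), with Xist (3.36 ± 0.48, adjusted p = 0.00141, 99.3 ± 70.4 against 7.86 ± 1.76 FPKM) higher. Lhx5 (-3.17 ± 0.44, adjusted p = 0.00127, 0.314 ± 0.268 against 10.5 ± 1.56 FPKM), a homeobox gene, was lower. Of the T-cell list 0 of 24 passed (0 passed adjusted over the list alone), and Lef1 stood at 391 ± 238 against 141 ± 22.4 FPKM (1.37 ± 0.55, adjusted p = 0.268). The T-cell list passed camera with the preset correlation only (adjusted p = 0.494 with an estimated correlation). The count is 2056 without combination pool A, 72 without combination pool B, 31 without chemotherapy pool A and 52 without chemotherapy pool B. A fit of the LSC pools alone passed 9, and neither Xist nor Lhx5 passed in it. With quantile scaling, a shift of 0.16 from a median of -0.14, 36 genes were higher and 65 lower.

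Does adding chemotherapy to low DXR change LSC? This comparison was added after the data were seen. Part of the neutrophil markers were higher in the combination: 6 of 16 were higher and 10 did not pass (12 passed adjusted over the list alone), with Elane (6.17 ± 0.71, adjusted p = 0.00012, 208 ± 163 against 1.77 ± 2.51 FPKM) and Mpo (8.40 ± 1.19, adjusted p = 0.00108, 2610 ± 971 against 26.2 ± 37.1 FPKM), the myeloperoxidase of granule precursors. Cd34 (3.27 ± 0.43, adjusted p = 0.000525, 30.2 ± 2.17 against 2.55 ± 2.22 FPKM) was higher among the stem and progenitor genes (2 of 23 were higher and 21 did not pass, 10 passed adjusted over the list alone). Both lists lost their camera calls (adjusted p = 0.343 and adjusted p = 0.749 with an estimated correlation). In all 388 genes passed, 260 higher and 128 lower, with 79 without combination pool A, 2266 without combination pool B and 232 without low DXR pool A. A fit of the LSC pools alone passed 2, with 0 neutrophil markers and 0 stem and progenitor genes, and Elane, Mpo and Cd34 did not pass in it.

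What does chemotherapy do to HSPC? Few genes passed, among them a neutrophil marker that rose and a pair of megakaryocyte genes that fell. Of the neutrophil markers 1 of 16 rose and 15 did not pass (6 passed adjusted over the list alone), the passing gene being Fcnb (4.61 ± 0.71, adjusted p = 0.0016, 42 ± 6.64 against 0.642 ± 0.408 FPKM). Of the megakaryocyte genes 2 of 9 fell and 7 did not pass (2 passed adjusted over the list alone), among them Ppbp (-1.56 ± 0.21, adjusted p = 0.000502), a platelet chemokine, whose call was lost with a pseudocount of 0.1 FPKM. Fitting HSPC pools alone, 0 megakaryocyte genes fell. Both lists passed camera with the preset correlation only (adjusted p = 0.226 and adjusted p = 0.121 with an estimated correlation). In all 141 genes passed, 79 that rose and 62 that fell, and 64, 75 or 89 passed without chemotherapy pool A, chemotherapy pool B or vehicle pool A. The median of all genes lies at 0.18, and quantile scaling, a shift of -0.17, gives 33 that rose and 76 that fell. Without chemotherapy pool A (28 and 36) or vehicle pool A or B (35 and 54, 34 and 69) more fell too.

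What does low DXR do to HSPC? Part of the T-cell, Wnt and checkpoint genes rose, and part of the megakaryocyte and respiratory chain genes fell. In the T-cell list 12 of 24 rose and 12 did not pass (12 passed adjusted over the list alone), in the Wnt list 4 of 17 rose and 13 did not pass (4 passed adjusted over the list alone) and in the checkpoint list 6 of 19 rose and 13 did not pass (6 passed adjusted over the list alone). Fitting HSPC pools alone, 6 T-cell and 3 checkpoint genes rose. Examples are Lef1 (2.95 ± 0.55, adjusted p = 0.00173, 98.7 ± 32.3 against 12.8 ± 4.47 FPKM), Tcf7 (3.68 ± 0.67, adjusted p = 0.00145, 104 ± 33 against 7.69 ± 0.702 FPKM) and Cd274 (2.03 ± 0.38, adjusted p = 0.00174, 47.6 ± 8.05 against 10.9 ± 0.431 FPKM). Cma1 (9.20 ± 1.65, adjusted p = 0.00136, 11600 ± 1710 against 79.7 ± 110 FPKM), a mast cell protease, rose. In oxidative phosphorylation 9 of 20 fell and 11 did not pass (13 passed adjusted over the list alone), and of the megakaryocyte genes 1 of 9 rose, 4 fell and 4 did not pass (7 passed adjusted over the list alone), with Pf4 (-5.48 ± 1.02, adjusted p = 0.00173) and Gp1bb (-2.64 ± 0.27, adjusted p = 5.21e-06) falling. Xist (5.71 ± 0.48, adjusted p = 7.09e-07) rose with these changes. The T-cell, Wnt, checkpoint and oxidative phosphorylation calls were lost, each at adjusted p = 0.451 with an estimated correlation. In all 2582 genes passed, 1375 that rose and 1207 that fell, with 1344 without low DXR pool B, 925 without vehicle pool A and 975 without vehicle pool B. Quantile scaling gives 1203 that rose and 1464 that fell.

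What does the clinical dose do to HSPC? Most of the MHC class II, neutrophil, megakaryocyte and mitochondrially encoded genes on the lists fell, and 7 of the 14 glycolysis genes rose. Of MHC class II 7 of 9 fell and 2 did not pass (7 passed adjusted over the list alone), with H2-Aa (-8.39 ± 1.66, adjusted p = 0.000926) and its regulator Ciita (-3.13 ± 0.58, adjusted p = 0.000522). Of the neutrophil markers 10 of 16 fell and 6 did not pass (12 passed adjusted over the list alone), where 4 fell without the 2 shallow pools, and of the mitochondrially encoded transcripts 9 of 10 fell and 1 did not pass (9 passed adjusted over the list alone). In glycolysis 7 of 14 rose, 1 fell and 6 did not pass (9 passed adjusted over the list alone), and of the megakaryocyte genes 2 of 9 rose, 6 fell and 1 did not pass (8 passed adjusted over the list alone). With quantile scaling 3 megakaryocyte genes rose and 5 fell, and the list has adjusted p = 0.527 with an estimated correlation. Pf4, Ppbp and Gp1bb were listed at 0 in both clinical DXR pools, while Itga2b (4.95 ± 0.61, adjusted p = 9.69e-06), an integrin of platelets, rose. Kit (2.89 ± 0.45, adjusted p = 0.000104, 351 ± 237 against 40.9 ± 1.79 FPKM), the stem cell factor receptor of stem and mast cells, Cd274 (2.36 ± 0.38, adjusted p = 0.000143, 59.8 ± 9.04 against 10.9 ± 0.431 FPKM) and Xist (5.15 ± 0.48, adjusted p = 5.18e-07) rose. The mast cell protease Cma1 (11.84 ± 1.65, adjusted p = 3.81e-05, 97500 ± 93000 against 79.7 ± 110 FPKM) rose with them, and Cpa3, another one, takes the most reads of any gene in both clinical DXR libraries. The MHC class II, neutrophil and mitochondrial lists passed camera with the preset correlation only (each adjusted p = 0.773 with an estimated correlation). In all 5751 genes passed, 2057 that rose and 3694 that fell, with 3483 without vehicle pool A and 3471 without vehicle pool B. The median of all genes lies at -0.27, and quantile scaling, a shift of 0.35, gives 2983 that rose and 2713 that fell.

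What does the combination do to HSPC? Against vehicle 106 genes rose and 137 fell, 243 in all. Without the 2 shallow pools 893 passed, 544 that rose and 349 that fell, and with every library as a unit 1759 rose and 1156 fell. Il7r (3.04 ± 0.44, adjusted p = 0.000606, 1050 ± 160 against 129 ± 7.77 FPKM), the interleukin-7 receptor, rose, Gstm6 (-3.06 ± 0.37, adjusted p = 0.000103) fell, and Xist (5.13 ± 0.48, adjusted p = 6.24e-06, 103 ± 67.3 against 1.51 ± 0.105 FPKM) rose. A fit of the HSPC pools alone passed 36 genes, without Il7r and Gstm6. In the T-cell list 1 of 24 rose and 23 did not pass (3 passed adjusted over the list alone) (camera adjusted p = 0.00114, adjusted p = 0.484 with an estimated correlation). The count is 114 without combination pool B, 120 without vehicle pool A and 152 without vehicle pool B. Against chemotherapy alone 562 genes passed, 166 higher and 396 lower, among them Cxcr6 (5.74 ± 0.67, adjusted p = 6.33e-05, 682 ± 128 against 14.1 ± 4.2 FPKM), a homing receptor of T and NK cells and Xist (5.15 ± 0.48, adjusted p = 8.55e-06). That count is 163 without combination pool B, 152 without chemotherapy pool A and 191 without chemotherapy pool B, and with quantile scaling, a shift of 0.12 from a median of -0.12, it splits into 230 higher and 191 lower. Against low DXR alone, a comparison added later, 225 genes passed, 71 higher and 154 lower, or 77 without combination pool A. There the megakaryocyte genes (2 of 9 were higher and 7 did not pass, 6 passed adjusted over the list alone) include Gp1bb (2.08 ± 0.27, adjusted p = 0.000316, 11.5 ± 6.13 against 1.72 ± 0.15 FPKM), which did not pass in a fit of the HSPC pools alone.

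Do LSC and HSPC respond differently? For chemotherapy the LSC change exceeded the HSPC change in part of the antigen presentation genes: Psmb8 (3.24 ± 0.34, adjusted p = 3.43e-05) and H2-DMb1 (3.74 ± 0.60, adjusted p = 0.0033). In MHC class I 4 of 13 were higher and 9 did not pass (7 passed adjusted over the list alone), and in glycolysis 3 of 14 were higher and 11 did not pass (12 passed adjusted over the list alone) (adjusted p = 0.18 and adjusted p = 0.351 with an estimated correlation). For low DXR the difference was larger in Psmb8 (4.89 ± 0.34, adjusted p = 1.94e-07) and of the other sign in Ermap (-7.27 ± 1.29, adjusted p = 0.000999), Car1 (-4.99 ± 0.79, adjusted p = 0.000451) and Kit (-4.39 ± 0.63, adjusted p = 0.000209). Of the erythroid markers 1 of 15 was higher, 6 were lower and 8 did not pass (8 passed adjusted over the list alone), and in ribosome biogenesis 4 of 15 were lower and 11 did not pass (8 passed adjusted over the list alone) (adjusted p = 0.902 and adjusted p = 0.696 with an estimated correlation). The low DXR response of Lef1 (1.23 ± 0.77, adjusted p = 0.306) and of Cd274 (0.30 ± 0.54, adjusted p = 0.765) did not differ detectably between LSC and HSPC. For chemotherapy 350 genes passed, 328 above and 22 below 0. A fit of LSC and HSPC alone passed 66, with 1 MHC class I, 0 glycolysis and 0 neutrophil genes among them. Without LSC chemotherapy pool A or B the count is 95 or 139, and without HSPC chemotherapy pool A or B it is 100 or 144. Without HSPC vehicle pool A or B it is 137 or 157, and without LSC vehicle pool A it is 217. For low DXR 3094 genes passed, 2014 above and 1080 below 0 (1724 in a fit of LSC and HSPC alone, with 4 erythroid genes and 1 of ribosome biogenesis lower), with 1904 without HSPC vehicle pool A and 1890 without HSPC vehicle pool B. Quantile scaling gives 171 above and 111 below for chemotherapy (median 0.24, shift -0.32), and 1618 above and 1671 below for low DXR (median 0.18, shift -0.21).

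What does chemotherapy do to blasts? Part of the B-cell genes fell and part of the monocyte genes rose. Of the B-cell markers 3 of 11 fell and 8 did not pass (7 passed adjusted over the list alone), with Cd22 (-2.50 ± 0.26, adjusted p = 9.48e-06, 7.9 ± 1.03 against 50.9 ± 19.4 FPKM), an inhibitory B-cell lectin, and Ebf1 (-2.72 ± 0.33, adjusted p = 5.92e-05, 6.75 ± 1.53 against 50.6 ± 17.3 FPKM). Both lost their call with a pseudocount of 0.1 FPKM. The list kept its camera call with an estimated correlation (adjusted p = 0.00243). Of the monocyte genes 3 of 16 rose and 13 did not pass (5 passed adjusted over the list alone), at adjusted p = 0.0879 with an estimated correlation. For MHC class II 1 of 9 fell and 8 did not pass (2 passed adjusted over the list alone), also at adjusted p = 0.0879 with an estimated correlation. Fitting blast pools alone, 8 B-cell and 8 MHC class II genes fell, and 9 monocyte and 4 neutrophil genes rose. In all 264 genes passed, 103 that rose and 161 that fell, with 124 without chemotherapy pool A, 148 without vehicle pool A and 175 without vehicle pool B. The median of all genes lies at 0.12, and quantile scaling, a shift of -0.13, gives 71 that rose and 203 that fell. The balance turns in a fit of the blast pools alone (430 rose and 379 fell), without the 2 shallow pools (388 and 309), without chemotherapy pool B (137 and 112) and with every library as a unit (1494 and 704).

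What do both doses of DXR do to blasts? Most B-cell and MHC class II genes fell at either dose. At the low dose 9 of 11 fell and 2 did not pass (9 passed adjusted over the list alone) in the B-cell list, with Cd79b (-11.35 ± 1.32, adjusted p = 1.12e-05, 15.5 ± 6.86 against 14700 ± 326 FPKM). For MHC class II 8 of 9 fell and 1 did not pass (9 passed adjusted over the list alone), with H2-Aa (-10.85 ± 1.66, adjusted p = 0.00026, 15 ± 8.97 against 14400 ± 192 FPKM) and Ciita (-6.17 ± 0.58, adjusted p = 8.03e-07). The clinical dose gave the same counts. Interferon genes rose at the clinical dose: 4 of 20 rose and 16 did not pass (5 passed adjusted over the list alone), with Ifit1 (2.42 ± 0.31, adjusted p = 4.54e-05, 9.74 ± 2.42 against 1.11 ± 0.56 FPKM) and Bst2 (2.52 ± 0.36, adjusted p = 0.000138). Il7r (2.59 ± 0.44, adjusted p = 0.000922, 6140 ± 1210 against 1010 ± 95.9 FPKM) rose, and the dividing-cell gene Mki67 (-2.46 ± 0.36, adjusted p = 0.000189) fell. These calls for the B-cell, MHC class II and interferon lists held with an estimated correlation (low dose adjusted p = 0.00136 and adjusted p = 0.0251, clinical dose adjusted p = 0.000936, adjusted p = 0.0141 and adjusted p = 0.0364). Markers of other cells moved too: at the low dose in the NK list 4 of 11 fell and 7 did not pass (7 passed adjusted over the list alone) and in the monocyte list 2 of 16 fell and 14 did not pass (5 passed adjusted over the list alone) (each adjusted p = 0.349 with an estimated correlation). Fitting blast pools alone, 8 NK and 7 monocyte markers fell there, and 1 of each list rose. At the clinical dose, of the T-cell markers 2 of 24 rose and 22 did not pass (3 passed adjusted over the list alone) (adjusted p = 0.344 with an estimated correlation). In that fit 17 T-cell markers rose. Xist (4.22 ± 0.48, adjusted p = 9e-06, 82.9 ± 6.58 against 3.96 ± 2.62 FPKM) rose at the low dose beside the B-cell and MHC class II changes, and also at the clinical dose (3.63 ± 0.48, adjusted p = 6.27e-05).

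The low dose passed 1208 blast genes, 347 that rose and 861 that fell, with 575 without low DXR pool A, 548 without low DXR pool B and 457 without vehicle pool A. Quantile scaling of these blast pools gives 586 that rose and 801 that fell. The clinical dose passed 768 blast genes, 271 that rose and 497 that fell, with 391 without clinical DXR pool A, 414 without clinical DXR pool B and 416 without vehicle pool A. A fit of the blast pools alone gives 1450 that rose and 1406 that fell at the clinical dose.

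**Figure D3:**
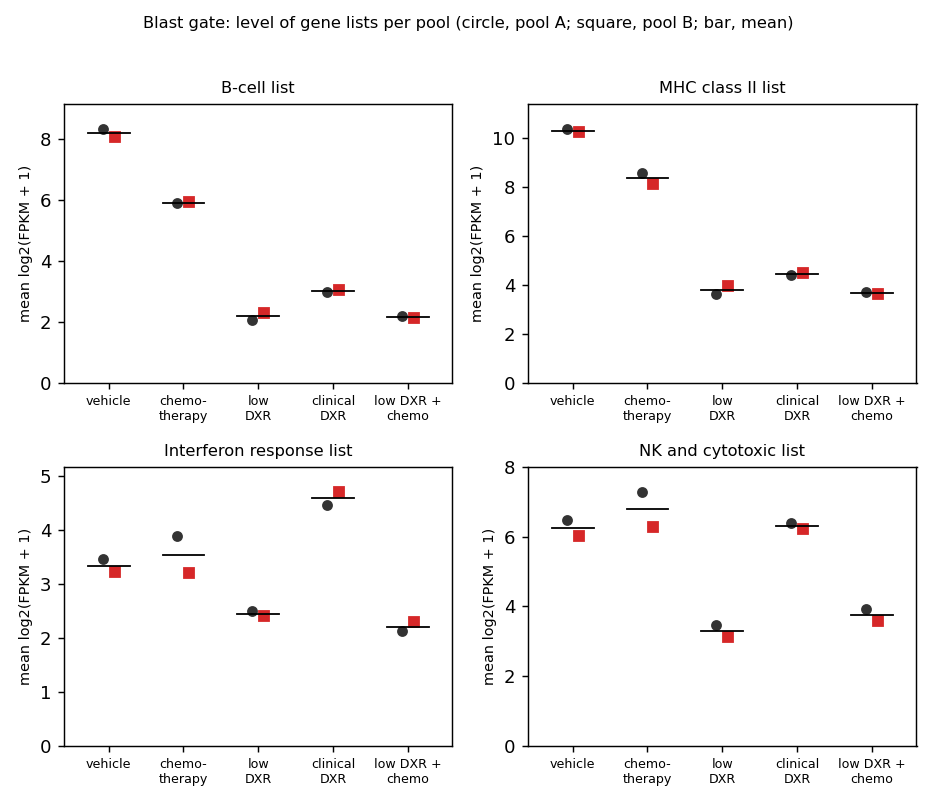
Mean log2(FPKM + 1) of gene lists in each blast pool by treatment, circles pool A, squares pool B, bars the mean of 2 pools. The B-cell list runs from 7.87 to 8.46 over vehicle libraries and from 5.68 to 6.13 after chemotherapy. After low DXR it runs from 1.68 to 2.77, after clinical DXR from 2.29 to 3.99 and after the combination from 1.99 to 2.42.

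What does the combination do to blasts? Most B-cell and MHC class II genes fell, and part of the class I, chemokine, interferon and NK genes. Of the B-cell markers 9 of 11 fell and 2 did not pass (9 passed adjusted over the list alone), with Cd79b (-10.53 ± 1.32, adjusted p = 2.74e-05), and Pax5 was listed at 0 in both combination pools. For MHC class II 8 of 9 fell and 1 did not pass (9 passed adjusted over the list alone), with H2-Aa (-10.90 ± 1.66, adjusted p = 0.000259). Both lists held with an estimated correlation (adjusted p = 0.000687 and adjusted p = 0.0122). Of the chemokine and adhesion genes 6 of 15 fell and 9 did not pass (6 passed adjusted over the list alone), with Icam1 (-3.22 ± 0.39, adjusted p = 1.81e-05), and Xist (3.90 ± 0.48, adjusted p = 2.27e-05) rose. In class I 4 of 13 fell and 9 did not pass (8 passed adjusted over the list alone). Among interferon genes 4 of 20 fell and 16 did not pass (4 passed adjusted over the list alone). Of the NK markers 3 of 11 fell and 8 did not pass (6 passed adjusted over the list alone). Fitting blast pools alone, 7 class I and 7 interferon genes fell. There 1 chemokine gene rose and 10 fell, and 1 NK marker rose and 7 fell. The class I, chemokine, interferon and NK lists lost their camera calls (adjusted p = 0.128, adjusted p = 0.117, adjusted p = 0.117 and adjusted p = 0.38 with an estimated correlation). In all 979 genes passed, 205 that rose and 774 that fell, with 510 without combination pool A, 522 without combination pool B and 444 without vehicle pool A. Quantile scaling of these blast pools gives 343 that rose and 727 that fell.

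Against chemotherapy alone, combination blasts had lower B-cell (8 of 11 were lower and 3 did not pass, 8 passed adjusted over the list alone), MHC class II (7 of 9 were lower and 2 did not pass, 7 passed adjusted over the list alone) and monocyte genes (6 of 16 were lower and 10 did not pass, 7 passed adjusted over the list alone). Cd22 (-2.42 ± 0.26, adjusted p = 3.22e-05, 0.663 ± 0.187 against 7.9 ± 1.03 FPKM), Ciita (-5.07 ± 0.58, adjusted p = 4.9e-05) and Lyz2 (-5.17 ± 0.70, adjusted p = 0.000266) are examples, and Xist (3.31 ± 0.48, adjusted p = 0.00043) was higher beside them. The B-cell, MHC class II and monocyte lists held with an estimated correlation (adjusted p = 0.00498, adjusted p = 0.0429 and adjusted p = 0.0429). Markers of other cells were lower too: of the NK list 3 of 11 were lower and 8 did not pass (7 passed adjusted over the list alone) and of the neutrophil list 2 of 16 were lower and 14 did not pass (10 passed adjusted over the list alone) (adjusted p = 0.294 and adjusted p = 0.184 with an estimated correlation). Fitting blast pools alone, 11 monocyte, 9 NK and 2 neutrophil markers were lower. In all 587 genes passed, 32 higher and 555 lower, with 239 without combination pool A, 230 without combination pool B and 183 without chemotherapy pool A. With quantile scaling, a shift of 0.22 from a median of -0.11, 86 were higher and 388 lower. Against low DXR alone, a comparison added later, 17 blast genes passed, 12 higher and 5 lower. Few or no genes passed when 1 of its pools was left out. By limma 901 genes of the full comparison have an unadjusted p under 0.05, about the share of the tested genes that chance alone gives.

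Of the 675 list tests, 256 passed camera with the preset correlation and 14 of these also with an estimated one. The 14 are the wild-type HSPC comparison (B-cell, FOXO, megakaryocyte), the B-cell list in blasts for each treatment against vehicle and for the combination against chemotherapy, MHC class II in blasts given DXR or the combination, interferon genes in blasts at the clinical dose, and monocyte genes between combination and chemotherapy blasts. Those of wild-type HSPC rest on a single wild-type unit. The effect of chemotherapy with and without low DXR can be compared across genes without shared libraries. Its correlation between chemotherapy minus vehicle and combination minus low DXR is -0.04 in LSC, -0.06 in HSPC and 0.17 in blasts, over genes that are not independent replicates. Of the 2248 genes that rose in LSC with chemotherapy, 45.7% also lie above 0 in the combination minus low DXR, where 51.3% of all genes do. In HSPC the share is 70.9% of 79 genes, where 46.8% of all genes do, and in blasts 71.8% of 103, where 48% do. Of the genes that fell with chemotherapy, 14.6% of 212 in LSC, 32.3% of 62 in HSPC and 34.8% of 161 in blasts also lie below 0 there, where 47.4%, 51.5% and 48% of all genes do.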

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

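Of the tests in this part, that of the X and Y chromosomes was written before its result was seen. The other 10 were chosen after seeing the results they measure.

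Some libraries stand apart from the others of their group. In depth, blast clinical DXR library A3 has 22.6 M reads in genes where the next has 9.04 M. HSPC chemotherapy library B2 has 14.4 M where the next has 12 M. In the level of the neutrophil list, blast low DXR library A1 lies at 1.51 where the next lies at 0.402, and HSPC vehicle library B1 lies at 5.2 where the next lies at 4.47. These are 4 of 55 pairs of a group and a measure, over 5 measures, and chance picks out about 5% of groups.

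Responses differ between cell types. By a test of the difference itself, 350 genes changed differently with chemotherapy in LSC and HSPC, and 3094 with low DXR.

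One pattern is that DXR pools differ from vehicle pools along the same split as the Y-linked transcripts. Blast clinical DXR pool B keeps 0.404 of the vehicle level of Y-linked genes. The 17 B-cell and MHC class II genes that fell with low DXR keep a median of 0.00697, at most 0.117. For them this argues against male vehicle-like cells as carriers and against sex. Genes on X or Y make up 3.09% of those that passed in LSC given low DXR. At 3.42% of those tested they could not be the bulk, so the test decides nothing on sex. Neither sex nor an experiment or batch along the split can be told from treatment. Of the 12 vehicle or chemotherapy pools, 0 lie under 100 FPKM of Ddx3y. By Ddx3y and Xist, sex mostly follows the split, unlike the stated even mix.

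Another pattern is that vehicle LSC are high in early erythroid and low in T-cell genes. The 4 haemoglobin genes lie a median of 5.69 log2 units higher in LSC given low DXR (5.52 to 6.16), which argues against an excess of haemoglobin-making erythroid cells in vehicle LSC over low DXR LSC. Vehicle LSC libraries have a median of 11.9 M reads and the other LSC libraries 12.4 M, which argues against depth. An excess of haemoglobin-making cells stays open against other groups, where the genes move the way it needs: a median of -1.70 in chemotherapy LSC (-2.71 to -0.84), -5.63 in clinical DXR LSC (-6.98 to -3.54) and -3.63 in vehicle HSPC (-4.06 to -2.70), relative to vehicle LSC. Both pools lie below both vehicle LSC pools in 4, 3 and 4 of the 4 genes, by mean log2 values, although mean FPKM of Hba-a2 reaches 72.1 in HSPC pool B and 62 in vehicle LSC pool A. Of the 18 T-cell genes that passed, 17 are higher with low DXR. The SD of their changes, 1.8, decides nothing on a common factor, as the scale understates weakly expressed genes. A lower share of T-lineage cells in the vehicle gate stays open. A biological effect of the drug on LSC was not separated from it.

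The last pattern is that LSC given the clinical dose list many cell cycle genes near 0. Of the 25 genes on the list, 13 hold under 0.5 of the reads expected at the library's own depth from the lower low DXR pool, in both clinical DXR libraries (Poisson p under 0.001 in each, at least 29 reads expected), which argues against low depth for those 13. Technical libraries vary by more than counting error, so this p speaks to depth alone. The other 12 genes were not short in both. Summed, the 9 that did not fall reach 2.36 of expected reads in pool A and 0.792 in B. The whole list reaches 1.08 and 0.327. This count by gene replaced sums over the list and the 16 genes that fell, both already seen. Few cells behind the libraries stay open. At 705357 reads the clinical DXR libraries detect 0.893 to 0.905 times as many genes as the lower low DXR library over 10 draws. This spans the bound set. A single draw was used before. A biological arrest of division was not tested on its own.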

How the results depend on the processing

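The pseudocount, filter, quantile, library, threshold, block and leave-one-out alternatives were set before the data were examined. Leaving out the 2 shallow pools, fitting cell types alone, the combination against low DXR and the repeated list tests were chosen after seeing the data. Counts are of genes past the threshold, printed where they moved by more than 1.5 times, and the cause was not tested. With 2 pools per group a lone pool is assumed to vary like the other groups. Depth limits the LSC and HSPC clinical DXR pools B, at 0.705 and 1.095 times 1e6 reads. Of 256 list calls with the preset correlation, 28 were lost with quantile scaling and 25 without the 2 shallow pools, and 10 of 235 with cell types alone, with 0 turned in direction. With an estimated correlation 242 of the 256 were lost. Besides the turns given with the results, the side with more genes turned as follows. In LSC clinical against low DXR came to 3406 higher and 3255 lower without the shallow pools and to 2493 and 2451 without clinical DXR pool B. In HSPC low DXR came to 483 that rose and 492 that fell without vehicle pool B. With a pseudocount of 0.1 FPKM HSPC came to 32 and 36 for chemotherapy and 66 and 64 for the combination, and an adjusted p under 0.001 gave 12 and 22 for chemotherapy. With every library as a unit blasts came to 2854 and 2808 for low DXR and 2515 and 2204 for clinical DXR. Combination against low DXR came there to 1438 higher and 1449 lower in LSC and 868 and 892 in blasts.

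Taking every library as a unit, which counts technical libraries as replicates, raised the counts: without drug 8550 for LSC against HSPC, 9576 for LSC against blasts, 1912 for HSPC against wild type and 3767 for blasts against wild type. In LSC it came to 7227 for chemotherapy, 6903 for the combination, 3385 for combination against chemotherapy and 2887 for combination against low DXR. In HSPC it came to 2235 for chemotherapy, 5289 for low DXR, 8652 for clinical DXR, 2915 for the combination, 4796 for combination against chemotherapy and 1569 for combination against low DXR. In blasts it came to 2198 for chemotherapy, 5662 for low DXR, 4719 for clinical DXR, 4606 for the combination, 3122 for combination against chemotherapy and 1760 for combination against low DXR. For differences of effect it came to 4393 for chemotherapy and 6290 for low DXR.

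An adjusted p under 0.001, a stricter threshold, lowered the counts: without drug 1240 for LSC against HSPC, 2057 for LSC against blasts, 73 for HSPC against wild type and 83 for blasts against wild type. In LSC this left 462 for chemotherapy, 1793 for low DXR, 3934 for clinical DXR, 386 for the combination, 13 for combination against chemotherapy, 21 for combination against low DXR and 924 for clinical against low DXR. In HSPC this left 34 for chemotherapy, 329 for low DXR, 1669 for clinical DXR, 59 for the combination, 75 for combination against chemotherapy and 27 for combination against low DXR. In blasts this left 75 for chemotherapy, 360 for low DXR, 266 for clinical DXR, 343 for the combination, 113 for combination against chemotherapy and 0 for combination against low DXR. For differences of effect this left 16 for chemotherapy and 423 for low DXR.

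Leaving the 2 shallow clinical DXR pools out of the fit raised the counts: without drug 6928 for LSC against HSPC, 487 for HSPC against wild type and 1503 for blasts against wild type. In LSC this gave 4999 for chemotherapy, 5110 for the combination, 1068 for combination against chemotherapy, 1841 for combination against low DXR and 6661 for clinical against low DXR. In HSPC this gave 280 for chemotherapy, 5053 for low DXR, 893 for the combination, 2028 for combination against chemotherapy and 1046 for combination against low DXR. In blasts this gave 697 for chemotherapy, 2811 for low DXR, 1875 for clinical DXR, 2261 for the combination, 1268 for combination against chemotherapy and 70 for combination against low DXR. For differences of effect this gave 1175 for chemotherapy and 6052 for low DXR. In HSPC given the clinical dose, Kdr (-0.02) and Cdh5 (-0.12) reversed there, and likewise without clinical DXR pool B. Without clinical DXR pool A they lie at 3.43 and 5.15.

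A fit of the compared cell types alone lowered the LSC and HSPC counts given here and raised those of blasts except combination against low DXR: without drug 2846 for LSC against HSPC. In LSC such a fit gave 619 for chemotherapy, 2756 for low DXR, 48 for the combination, 9 for combination against chemotherapy, 2 for combination against low DXR and 1728 for clinical against low DXR. In HSPC such a fit gave 30 for chemotherapy, 36 for the combination, 136 for combination against chemotherapy and 44 for combination against low DXR. In blasts such a fit gave 809 for chemotherapy, 3921 for low DXR, 2856 for clinical DXR, 2929 for the combination, 1506 for combination against chemotherapy and 0 for combination against low DXR. For differences of effect such a fit gave 66 for chemotherapy and 1724 for low DXR.

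A pseudocount of 0.1 FPKM gave in LSC 75 for combination against chemotherapy. In HSPC it gave 68 for chemotherapy, 130 for the combination, 270 for combination against chemotherapy and 140 for combination against low DXR. In blasts it gave 149 for chemotherapy and 6 for combination against low DXR. Testing all genes with no filter gave without drug 360 for HSPC against wild type. In LSC it gave 408 for combination against chemotherapy. In blasts it gave 31 for combination against low DXR. Quantile scaling gave in LSC 101 for combination against chemotherapy.

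The pool letters A and B are not said to mark a shared batch. With the letter as a block, the count became in LSC 146 for combination against chemotherapy. In blasts it gave 2 for combination against low DXR. The block moved no other count by more than 1.5 times. Changes of pools with the same letter correlate at a median r of 0.01 in LSC and 0.05 in HSPC and blasts, and 0, 1 and 2 of 10 pairs of groups exceed 0.1.

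Leave-one-out ranges without drug are 2422 to 3074 for LSC against HSPC, 3755 to 4742 for LSC against blasts, 169 to 247 for HSPC against wild type and 240 to 701 for blasts against wild type. In LSC they are 986 to 1562 for chemotherapy, 3648 to 4872 for low DXR, 6219 to 8517 for clinical DXR, 1048 to 4289 for the combination, 31 to 2056 for combination against chemotherapy, 79 to 2266 for combination against low DXR and 2310 to 5026 for clinical against low DXR. In HSPC they are 64 to 103 for chemotherapy, 925 to 1775 for low DXR, 3471 to 7087 for clinical DXR, 114 to 197 for the combination, 152 to 415 for combination against chemotherapy and 77 to 322 for combination against low DXR. In blasts they are 124 to 249 for chemotherapy, 457 to 1632 for low DXR, 391 to 729 for clinical DXR, 444 to 1029 for the combination, 183 to 579 for combination against chemotherapy and 0 to 7 for combination against low DXR. For differences of effect they are 95 to 308 for chemotherapy and 1890 to 2634 for low DXR.

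Of the 1182 calls of named genes, 135 were lost with the smaller pseudocount, 93 with no filter, 72 with quantile scaling, 44 with the block, 614 at the stricter threshold and 10 without the shallow pools. With cell types alone 289 of 1154 were lost, and over the leave-one-out fits 1170 of 5152.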

Other observations

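The values in this part were chosen after the data were seen, and none was tested. The wild-type libraries also hold Y-linked transcript: Ddx3y stands at 1430 FPKM in wild-type HSPC and 2080 in wild-type Lym cells.

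The mean level of the neutrophil list varies widely between libraries of some groups. It runs from 0.45 to 5.20 in blast vehicle libraries and from 2.93 to 8.63 in blasts after chemotherapy. In LSC it runs from 3.40 to 4.22 with vehicle, from 0.66 to 3.29 with low DXR and from 4.65 to 7.89 with the combination. In blasts it runs from 0.21 to 1.51 with low DXR and from 0.46 to 3.85 with the combination.

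At an equal depth of 705357 reads, HSPC chemotherapy libraries detect 14889 to 15270 genes and HSPC vehicle libraries 14148 to 14418. HSPC given the clinical dose detect 11474 to 11959. Among LSC, chemotherapy libraries detect 14890 to 15349 and vehicle libraries 12316 to 13236.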
